A study of Mus musculus and Gallus gallus and Xenopus tropicalis with 21 samples.

How the data were processed

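The series holds mRNA sequencing of brain, liver, kidney, heart and skeletal muscle from mouse, chicken, lizard, frog and pufferfish, 21 libraries in 20 groups of 1 species and 1 organ. Per the labels, the RNA of each organ was pooled from adult animals of both sexes, enriched for polyadenylated RNA, and treated with UNG before amplification to keep strand information. Pufferfish has brain only and lizard lacks liver. Mouse brain has 2 libraries.

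The deposited tables give, per gene and for 1 transcript per gene, a read count, an RPKM and a column named Mappability. Tests of the values showed that the authors' RPKM is the count divided by the Mappability of the gene, which thus serves as its length, and by the library total, and that the total it implies exceeds the deposited count total by 0.000567% to 0.0361%. Only genes with at least 1 read are listed, so a gene missing from a library was given a count of 0. The authors named Bowtie, TopHat and bedtools and the build mm9, without versions. The annotation release, the read length and the builds of the other species are not given in the sources used here, nor is whether counting used strand. In mouse the Mappability of a gene differs by a few positions between 3 sets of libraries, brain library 1, then brain library 2 with liver and heart, then kidney with skeletal muscle. In frog it differs between brain, heart and muscle on one side and liver and kidney on the other. Chicken and lizard each have 1 set.

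Of 20899 mouse Ensembl identifiers in the tables, 20275 were given a symbol from the GENCODE M21 annotation. That annotation lies on a later build than the counts, so only names and exon overlaps between neighbours were used, and no coordinates are given. The other species' identifiers have no symbols in the sources used here. The comparisons of named genes across species, 8 results in all, were therefore not run, nor were the 62 of 100 alternatives set for them. Transcripts of 223 of 235 named genes were found in that annotation, 19 of them overlapped by exons of other genes over more than 25% of their bases and 5 over more than 50%.

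Depth ran from 9750428 to 76169571 counts per library. At 1 CPM (counts scaled to the library's total) the half-width of the counting error was 22.5% to 62.8%, and at 50 CPM it was 3.18% to 8.88%. A count of 0 allows up to 3 counts, 0.0394 to 0.308 CPM depending on the library. Intervals are exact (Clopper-Pearson) at 95%, and intervals and floors cover counting error only, since reads were amplified. A fold against a group with no reads is a lower bound, taken at 3 counts over that group.

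Mouse brain was compared with each other mouse organ in edgeR 4.0.16 (R 4.3.3), with filterByExpr, TMM factors and the quasi-likelihood test, which left 18098 genes. The Benjamini-Hochberg adjusted p threshold was 0.05. The fit had 1 residual degree of freedom, from the brain libraries, with a biological coefficient of variation of 2.55%, and a lone organ library is taken to vary as those do. The prior of the quasi-likelihood test had infinite degrees of freedom, so each gene was given the spread of the common trend and not its own. CPM in these comparisons are TMM-scaled, and p values reported as 0 by the software are not printed. Simulated data were built from these counts with 1 mean profile for all libraries, 200 genes set to change and the brain spread given to every organ. There, changes of 2-fold were found in 79.4% to 86.4% of cases, of 4-fold in 85.1% to 95.3% and of 8-fold in 93.8% to 100%. False calls made up 1.63% to 5.06% of calls. These rates hold only where an organ varies as brain does and few genes change, and were not checked for broader changes. Fixed gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated. In that second version the smallest unadjusted p of 96 tests was 0.0907, for the heart list against heart. Its estimated correlation, -0.0417, was below the preset one. Other lists lay above the preset, with 0.423 for ribosomal proteins, 0.268 for immediate early and heat shock genes, 0.222 for endothelium and 0.201 for splicing regulators. Camera calls of such lists rest on the preset value. With 1 residual degree of freedom the second version could hardly call any list, so its failures do not decide whether a list differs. The 24 lists covered neurons, astrocytes and oligodendrocytes, liver secretion and hepatocyte identity, liver metabolism, kidney, heart, fast and slow skeletal muscle, shared sarcomere genes, splicing regulators, general splicing factors, the respiratory chain, fatty acid oxidation, glycolysis, ribosomal proteins, blood, smooth muscle, adipocytes, endothelium, immune cells, fibroblasts and matrix, exocrine pancreas, pituitary and choroid plexus, and immediate early and heat shock genes. No comparison had groups of 3 or more libraries, so no other groupings of the libraries were counted.

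Heart and skeletal muscle of mouse, 1 library each, were compared by TMM-scaled CPM alone. The median of each list was placed among 10000 random lists of genes matched on expression in 50 bins. Tested on simulated data, 2% of 100 random lists of 20 genes and 99% of 100 shifted ones fell in the outer 5% of that distribution. Within mouse, chicken, lizard and frog, the number of genes with at least 1 CPM and the share of counts in the 10 most abundant genes were ranked over organs, with the mouse brain libraries averaged. A permutation test with 100000 draws shuffled organs within each species, over all organs together and without a direction. On simulated data it gave p under 0.05 in 5% of 300 sets with no organ effect and in 100% of 100 sets with one. Similarity of organs was Pearson's r across genes of log2 CPM with 1 added. The heart and skeletal muscle pair was tested by exact enumeration of 6000 choices of 1 pair per species, one-sided, and these 3 tests were adjusted together. An organ-enriched gene had at least 10 CPM and at least 8 times every other organ, with 1 CPM added to each. Liver-enriched genes in other libraries were taken from these sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

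Lists, comparisons and the rule for named genes were set before the data were examined. The rule takes, for each mouse organ, the 4 genes of at least 50 CPM furthest above the highest other organ, up to 4 members of each list with the largest change in a comparison, the 8 splicing regulators with the smallest adjusted p, and the 5 genes furthest to each side between heart and skeletal muscle. Some genes that the rule takes are not reported here. Other genes named are said to be chosen after their values were seen. Alternatives were DESeq2 1.42.0 size factors in edgeR, library size alone, the DESeq2 Wald test, glmTreat against a log2 change of 1, no filter, removal of mitochondrial and the most abundant genes, each brain library left out, other CPM minimums, thinning to equal depth, the authors' RPKM, Spearman's rho, a pseudocount of 0.1 and each species left out. Added after seeing the data were the species with 1 set of mappable positions alone, the analysis without frog heart, removal of the 100 most abundant genes, thinning with genes counted at 1 CPM, each species left out for the organ similarity, and library size alone for heart against skeletal muscle. Splicing itself was not analysed here.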

Results

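Polyadenylated RNA was sequenced on the Illumina HiSeq from brain, liver, kidney, heart and skeletal muscle of adult vertebrates, each organ as an RNA pool from animals of both sexes. The series asks how transcript processing differs between organs and between vertebrate species, and the gene-level read counts are described here. The 21 libraries form 20 groups of 1 species and 1 organ each. Mouse (strain C57BL/6), chicken and frog have all 5 organs, lizard has all but liver, and pufferfish has brain only. Mouse brain has 2 libraries, and each of the other 19 groups has 1 library, so those values carry no replicate error.

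Counted reads came to 76169571 and 54645238 in the mouse brain libraries, and to 54983363 in liver, 17302549 in kidney, 33826462 in heart and 55730020 in skeletal muscle of mouse. In chicken they came to 27834383 in brain, 26198217 in liver, 34449705 in kidney, 26651705 in heart and 31178305 in skeletal muscle. In lizard they came to 36877498 in brain, 9750428 in kidney, 26053150 in heart and 43959301 in skeletal muscle. In frog they came to 13803809 in brain, 66754040 in liver, 43443131 in kidney, 17540118 in heart and 23202273 in skeletal muscle. The pufferfish brain library held 17361419. Between 13165 and 18008 genes had at least 1 read in a library.

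In the mouse brain libraries, Camk2a, a synaptic kinase, took 0.471% and 0.472% of all counts and Mbp, a myelin protein, 0.394% in each. Over 16593 genes with at least 10 counts, the mean squared difference between the brain libraries was 2.89 times that of counting error alone. Among 13116 deeply counted genes the log2 ratio between them had an SD of 0.12, 34 genes differed by more than 1.5-fold and 2 by more than 2-fold. Across genes, which are not independent replicates, Pearson's r was 0.999 and Spearman's rho 0.998. Both libraries come from pooled RNA, and whether their pools held different animals is not given in the sources used here.

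Mouse brain was compared with each other mouse organ to list the genes that set the organs apart. Snap25, which drives synaptic vesicle fusion, stood at 1679 CPM ± 41.0 (SD, n = 2) in brain with no read in liver, at least 21877-fold higher. Grin1, a glutamate receptor subunit, stood at 639 CPM, Tubb3, a neuronal tubulin, at 504 CPM and Nefl, a neurofilament protein, at 424 CPM, again with no read in liver. Exons of other genes cover 34.1% of the counted Grin1 and 32.8% of the counted Nefl transcript. All 24 neuronal genes measured were higher in brain. The 18 measured genes of astrocytes and oligodendrocytes were higher in brain too, among them the myelin gene Mobp at 104 CPM and the calcium-binding S100b at 83.0 CPM, neither with a read in liver.

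Liver held all 24 measured genes of secreted plasma proteins and hepatocyte identity above brain. The fibrinogen chain gene Fgb stood at 7621 CPM in liver and 0.352 CPM in brain, and the complement gene C8a and the clotting factor gene F9 stood at 948 and 208 CPM with no read in brain. C8a was at least 51418-fold higher in liver. All 22 genes of liver metabolism were higher in liver as well. Hgd, of tyrosine breakdown, stood at 1207 CPM and Slc10a1, the bile acid transporter, at 1059 CPM, neither with a read in brain. Hpd, the enzyme before Hgd in tyrosine breakdown, stood at 4133 CPM in liver.

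Of 22 glycolytic genes 12 were higher in brain and 9 in liver, and 17 and 5 with scaling by library size alone. The neuronal enolase Eno2 stood at 1189 CPM in brain against 0.256 CPM in liver, while the pyruvate kinase gene Pklr stood at 802 CPM in liver against 0.480 CPM in brain. Of 18 genes of fatty acid oxidation 17 were higher in liver, led by the regulator Ppara at 119 against 1.54 CPM and the mitochondrial transferase Cpt2 at 344 against 8.84 CPM. The respiratory chain genes were higher in liver in 25 of 26 cases (20 with library size alone, and 3 higher in brain), such as Sdhd at 212 against 41.0 CPM. Ribosomal protein genes, many of which share sequence with pseudogenes, were higher in liver in 41 of 47 cases and in 21 of 47 with scaling by library size alone, which placed 9 higher in brain.

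Of 18098 genes tested with edgeR's quasi-likelihood test, 8081 were higher in brain, 7567 were lower and 2450 did not pass an adjusted p of 0.05. Calls of at least 4-fold came to 5053 higher and 3272 lower, and edgeR's glmTreat, which asks for a change beyond 2-fold, left 5893 higher and 4855 lower. Camera, which sets a list against all other genes, called 10 of 24 lists, with an adjusted p of 5.07e-08 for the neuronal list, 7.86e-08 for the secreted and hepatocyte list, 4.11e-07 for liver metabolism, 3.06e-06 for the respiratory chain, 1.03e-04 for fatty acid oxidation and 1.10e-04 for the ribosomal proteins. With an estimated correlation these 10 had adjusted p from 0.529 to 0.671, and none passed. In all 4 comparisons that version has 1 residual degree of freedom and could hardly call any list, so it does not decide. Adjusted over the list alone, the counts given were the same. A lone organ library was taken to vary as the brain libraries do, whose spread is not known to include differences between animals, so in all 4 comparisons the calls are not shown to exceed variation between animals. With scaling by library size alone the median log2 change of all genes shifted by 0.81 towards brain and the brain side rose from 51.6% to 67.5% of calls.

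In the comparison with kidney, Slc34a1, the phosphate carrier of the proximal tubule, stood at 9539 CPM in kidney with no read in brain, at least 517249-fold higher, and Umod, the uromodulin gene of the thick ascending limb, at 3386 CPM. Cdh16, a kidney cadherin, stood at 1351 CPM and Slc5a2, the glucose carrier, at 472 CPM, both without a read in brain. The counted Cdh16 transcript is not in the annotation used, so its overlap with other genes was not checked. Exons of another gene cover 26.2% of the counted Slc5a2 transcript. All 23 genes of the kidney list were higher in kidney, and all 24 neuronal and 18 glial genes were higher in brain. Slc17a7, the vesicular glutamate transporter, stood at 2056 CPM ± 10.4 (SD, n = 2), the synaptotagmin Syt1 at 859 CPM and the astrocyte filament gene Gfap at 245 CPM, none with a read in kidney.

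All 22 genes of liver metabolism were higher in kidney than in brain, among them Pck1, of glucose synthesis, at 2952 against 0.562 CPM and Hgd at 405 CPM. Of 24 secreted and hepatocyte genes 22 were higher in kidney, led among those with brain reads by the transcription factor gene Hnf4a at 659 against 0.290 CPM. The 30 most abundant liver-enriched genes stood in kidney at a median of 0.949% of their liver level, with 73.3% of them within 2-fold of that median. All 18 fatty acid oxidation genes were higher in kidney, such as Acadm at 577 against 16.8 CPM, and so were 25 of 26 respiratory chain genes, such as Ndufb8 at 336 against 35.5 CPM. Of 22 glycolytic genes 12 were higher in brain and 9 in kidney. Ribosomal protein genes were higher in kidney in 31 of 47 cases, Rps20 at 178 against 23.9 CPM.

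The test called 7989 genes higher in brain and 7180 lower, and 2929 did not pass. Calls of at least 4-fold came to 4142 higher and 3305 lower, and glmTreat left 5229 higher and 4679 lower. Camera called 14 of 24 lists, with an adjusted p of 2.99e-08 for the kidney list, 5.12e-08 for the neuronal list, 1.22e-06 for liver metabolism, 3.98e-05 for the secreted and hepatocyte list and 4.41e-07 for the respiratory chain. With an estimated correlation these 14 had adjusted p from 0.529 to 0.683, and none passed. Adjusted over the list alone, the counts were the same except for 30 ribosomal genes higher in kidney. With scaling by library size alone the median log2 change of brain over kidney shifted by -0.13. The brain side then fell from 52.7% to 49.7% of calls, so the larger side depends on the scaling.

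In the comparison with heart, Tnni3, cardiac troponin I, stood at 2117 CPM in heart with no read in brain, at least 114787-fold higher, and Myl7, the atrial myosin light chain gene, at 290.5 CPM. The cardiac transcription factor genes Gata4 and Tbx20 stood at 319 and 148 CPM, also with no read in brain. All 25 genes of the heart list and all 22 sarcomere genes shared by heart and skeletal muscle were higher in heart. Mb, the myoglobin gene, stood at 5212 against 0.102 CPM, Ckm, the muscle creatine kinase gene, at 2081 against 0.0863 CPM, and Myl2, a slow and ventricular myosin light chain gene, at 4922 against 0.209 CPM. Of 9 slow muscle genes 7 were higher in heart and 2 in brain.

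All 26 respiratory chain genes and all 18 fatty acid oxidation genes were higher in heart than in brain, with Uqcrfs1, of complex III, at 502 against 46.6 CPM and Cpt1b, the muscle gate of fatty acid entry into mitochondria, at 1153 against 2.29 CPM. Exons of another gene cover 94.8% of the counted Cpt1b transcript on its own strand. Fabp3, a fatty acid carrier, stood at 127 against 2.29 CPM. The 7 mitochondrially encoded genes counted took 14.8% of heart counts (exact 95% interval 14.75 to 14.77), 3.34% of skeletal muscle counts, 2.92% of kidney, 2.22% of liver, and 1.47% and 1.46% of the brain libraries. Of 22 glycolytic genes 14 were higher in heart and 7 in brain, and 10 and 8 with scaling by library size alone. Eno3, the muscle enolase, stood at 1084 against 4.96 CPM and Aldoc, the brain aldolase, at 859 CPM in brain against 0.535 CPM.

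Brain held all 24 neuronal genes and 17 of 18 glial genes above heart, with Slc32a1, the inhibitory vesicle transporter, at 348 CPM ± 6.73 (SD, n = 2) and no read in heart. Of the secreted and hepatocyte list, 20 of 24 genes were higher in heart and 3 in brain, such as the complement gene C3 at 768 against 5.10 CPM, and 20 of 22 genes of liver metabolism were higher in heart. The 30 most abundant liver-enriched genes stood in heart at a median of 0.247% of their liver level, 73.3% of them within 2-fold of it. Ribosomal protein genes went both ways, 13 higher in brain and 20 higher in heart of 47. With scaling by library size alone 22 were higher in brain and 12 in heart.

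The test called 7524 genes higher in brain and 7354 lower, and 3220 did not pass. Calls of at least 4-fold came to 3814 higher and 2967 lower, and glmTreat left 4868 higher and 4364 lower. Camera called 16 of 24 lists, with an adjusted p of 2.59e-08 for the heart list, 1.93e-07 for the shared sarcomere list, 7.86e-08 for the respiratory chain, 5.57e-06 for fatty acid oxidation and 0.0486 for the slow muscle list. With an estimated correlation these 16 had adjusted p from 0.529 to 0.583, and none passed. Adjusted over the list alone, the counts were the same except for 12 ribosomal genes higher in brain. With scaling by library size alone the median log2 change of all genes shifted by 0.32 towards brain. The brain side then rose from 50.6% to 59.2% of calls.

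In the comparison with skeletal muscle, Myh4, the fastest myosin heavy chain gene, stood at 84349 CPM in muscle against 0.858 CPM in brain, Tnnt3, fast troponin T, at 22627 against 0.163 CPM, and Mylpf, the fast myosin light chain gene, at 10947 CPM with no read in brain, at least 593628-fold higher. Ampd1, the muscle AMP deaminase gene, stood at 1349.7 CPM and Myoz1, a Z-disc gene, at 4291 CPM, neither with a read in brain. All 25 fast muscle genes and 21 of 22 shared sarcomere genes were higher in muscle, Ckm reaching 46622 CPM against 0.0863 CPM. Exons of other genes cover 36.5% of the counted Ckm transcript. Of 9 slow muscle genes 7 were higher in muscle, such as Myoz2 at 55.2 CPM, and 2 in brain.

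Among glycolytic genes, Eno3 stood at 8190.2 against 4.96 CPM and Pgam2, the muscle phosphoglycerate mutase gene, at 3204 against 4.82 CPM, while Aldoc stood at 859 CPM in brain against 0.586 CPM and Eno2 at 1189 against 1.09 CPM. Of 22 glycolytic genes 14 were higher in muscle and 8 in brain. All 26 respiratory chain genes and 17 of 18 fatty acid oxidation genes were higher in muscle, with Cox5a, of complex IV, at 425 against 41.5 CPM and Cpt1b at 557 against 2.29 CPM. Exons of other genes cover 41.7% of the counted Cox5a transcript and 94.8% of that of Cpt1b. Ribosomal protein genes were higher in muscle in 34 of 47 cases, and in 21 with scaling by library size alone, which placed 12 higher in brain.

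All 24 neuronal and 18 glial genes were higher in brain than in muscle, with the GABA-synthesising enzymes Gad1 and Gad2 at 305 and 146 CPM and no read in muscle. The heart list was divided, with 16 of 25 genes higher in muscle and 6 in brain, among the latter the cardiac and brain calcium channel gene Ryr2 at 136 against 0.666 CPM. Of 24 secreted and hepatocyte genes 21 were higher in muscle, and of 22 liver metabolism genes 18. The 30 most abundant liver-enriched genes stood in muscle at a median of 0.156% of their liver level, 60% of them within 2-fold of it.

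The test called 7614 genes higher in brain and 7737 lower, and 2747 did not pass. Calls of at least 4-fold came to 4146 higher and 3210 lower, and glmTreat left 5159 higher and 4880 lower, so the larger side depends on the test. Camera called 15 of 24 lists, with an adjusted p of 7.64e-08 for the fast muscle list, 1.97e-06 for the shared sarcomere list, 2.72e-07 for the respiratory chain and 2.67e-04 for fatty acid oxidation, while the heart list had 0.0578, and 0.0400 with DESeq2 size factors, which called it. With an estimated correlation the 15 had adjusted p from 0.529 to 0.745, and none passed. Adjusted over the list alone, the counts given were the same. With scaling by library size alone the median log2 change of all genes shifted by 0.88 towards brain, the brain side rose from 49.6% to 68.3% of calls, and 4939 genes were lower in brain.

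No test of shared function was run on the mouse genes that stood furthest above every other organ. In brain they were Snap25 (ENSMUSG00000027273) at 2088 CPM, the neuropeptide precursor gene Vgf at 1290.1 CPM, the synaptic complexin gene Cplx1 at 1404 CPM and the calcium sensor gene Hpca at 1229.8 CPM, with no other organ above 0.694 CPM for any of these. In liver they included the acute phase genes Saa1 (ENSMUSG00000074115) and Saa2 at 1290.4 and 1582 CPM, close paralogs of each other, and Mat1a, which makes the methyl donor of the cell, at 4297 CPM against 18.9 CPM in kidney. In kidney they were the inositol oxygenase gene Miox (ENSMUSG00000022613) at 4089 CPM, the androgen-regulated Kap at 10300.4 CPM, Slc34a1 at 12944 CPM and the urate carrier gene Slc22a12 at 3381 CPM. In heart, they were the alpha myosin gene Myh6 (ENSMUSG00000040752) at 18192 CPM, Pln, which restrains the calcium pump, at 3510.3 CPM, cardiac troponin T gene Tnnt2 at 5241 CPM and the cardiac myosin-binding gene Mybpc3 at 5078 CPM. In skeletal muscle they were Myh4 (ENSMUSG00000057003) at 56787 CPM, the fast actinin gene Actn3 at 16108 CPM, Mylpf at 7370.1 CPM and the fast troponin C gene Tnnc2 at 10723 CPM. These are plain CPM without TMM factors. Exons of other genes on the other strand cover 84.6% of the counted Tnnc2, 64.8% of the counted Pln and 30.6% of the counted Slc22a12 transcript.

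Because the series is about splicing, the genes of 36 splicing regulators were compared between the mouse organs. The list, fixed beforehand, includes neuronal regulators, so how many are highest in brain depends in part on the choice of list. Some members were broad, such as Celf1, from 82.6 CPM in kidney to 197 CPM in heart. Brain held the highest level of 20 of them, heart of 6, skeletal muscle of 5, liver of 3 and kidney of 2. The neuronal regulator genes Celf4 (ENSMUSG00000024268), Celf5 (ENSMUSG00000034818), Rbfox3 (ENSMUSG00000025576) and Elavl3 (ENSMUSG00000003410) stood at 393 CPM ± 1.97 (SD, n = 2), 343, 335 and 246 CPM in brain, and none passed 1.87 CPM elsewhere. Rbm38 (ENSMUSG00000027510) and Rbm24 (ENSMUSG00000038132), regulators of striated muscle splicing, stood at 338 and 244 CPM in skeletal muscle and 224 and 236 CPM in heart, against 3.66 and 12.8 CPM in brain. Esrp2 (ENSMUSG00000084128), an epithelial regulator, stood at 212 CPM in liver and 65.3 CPM in kidney against 0.463 CPM in brain. Rbfox1 (ENSMUSG00000008658), which acts in neurons and muscle, stood at 307 CPM in skeletal muscle, 190.2 CPM in brain and 56.9 CPM in heart, and with scaling by library size alone its log2 difference of brain over muscle turned to 0.20.

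**Figure D1:**
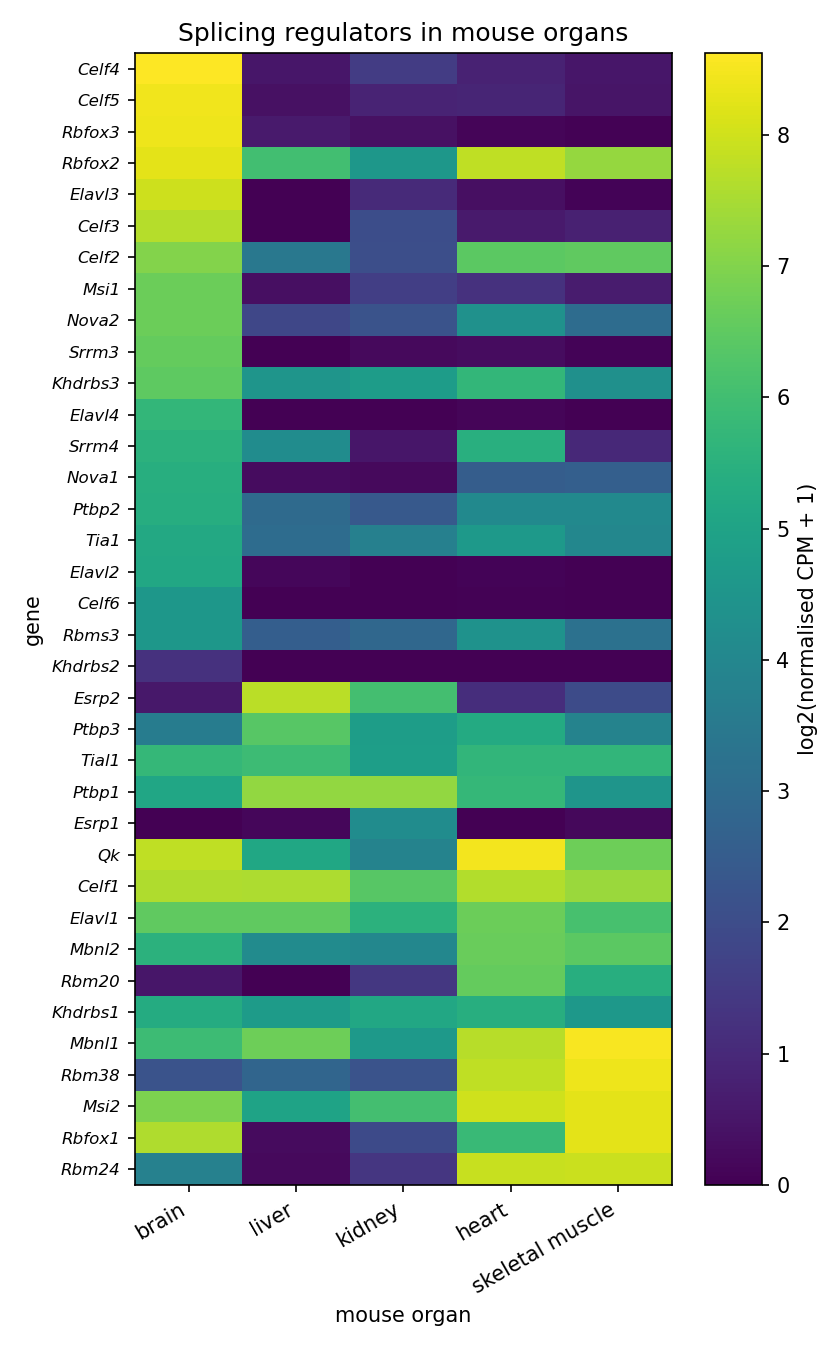
Heat map of the expression of 36 splicing regulator genes (log2 of TMM-scaled CPM with 1 added, colour) in the mouse organs, brain as the mean of 2 libraries and each other organ as 1 library, sorted by the organ with the highest level. Celf4, Celf5, Rbfox3 and Elavl3 are high in brain alone, Rbm38 and Rbm24 in heart and skeletal muscle, and Esrp2 in liver and kidney.

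The regulator list was higher in brain for 27 genes and lower for 7 against liver, 30 and 5 against kidney, 19 and 11 against heart, and 25 and 10 against skeletal muscle. These counts were the same adjusted over the list alone, and with scaling by library size alone they were 30 and 4, 29 and 5, 25 and 10, and 28 and 7. Of the 36 genes 18 were higher in brain in all 4 comparisons. The 2 lower in brain in all 4 were Esrp2 and the polypyrimidine tract-binding gene Ptbp3. Ptbp3 stood at 11.4 CPM in brain and 13.4 CPM in skeletal muscle. That gap is smaller than the median log2 shift of 0.88 towards brain with library size alone, so its direction against muscle depends on the scaling. Camera gave adjusted p of 0.00110, 2.45e-04, 0.129 and 0.0149 for liver, kidney, heart and muscle in turn, and with an estimated correlation adjusted p of 0.610, 0.583, 0.757 and 0.671. The estimated correlation of the regulator list, 0.201, was above the preset 0.01, so its camera calls rest on that preset. Among genes chosen after their values were seen, the muscleblind gene Mbnl1 stood at 374 CPM in skeletal muscle and 207 CPM in heart against 58.6 CPM in brain, and Rbm20, the titin splicing regulator, at 94.1 CPM in heart and 41.2 CPM in skeletal muscle. Ptbp1, the general repressor that neurons replace with Ptbp2, stood at 148 CPM in liver and 149 CPM in kidney against 33.4 CPM in brain, with exons of other genes over 29.2% of its counted transcript. Srrm4, a regulator of neuronal microexons, stood at 45.1 CPM in brain and 42.6 CPM in heart (adjusted p 0.223 by edgeR), 17.4 CPM in liver and under 1 CPM in kidney and skeletal muscle. The counted transcripts of Srrm4, Mbnl1, Rbm20 and Rbfox1 are not in the annotation used, so reads from overlapping genes were not ruled out for them.

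General splicing factors, the SR, hnRNP and snRNP genes, went both ways. Against liver 11 of 33 were higher in brain and 19 lower, against kidney 15 and 10, against heart 11 and 14, and against skeletal muscle 14 and 12. Hnrnpa2b1 stood at 126 CPM in brain, 284 CPM in liver, 264 CPM in heart and 319 CPM in skeletal muscle, and Snrpb at 49.3 CPM in brain and 174 CPM in muscle. Adjusted over the list alone the counts were the same, and camera called the list in none of the 4 comparisons, with adjusted p from 0.375 to 0.733 and, with an estimated correlation, from 0.670 to 0.796. With scaling by library size alone 24 were higher in brain and 4 lower against liver, 16 and 7 against heart, and 30 and 2 against skeletal muscle, so the direction for this list depends on the scaling.

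Between heart and skeletal muscle of mouse, Myh6 stood at 18291 CPM in heart against 2.91 CPM in skeletal muscle, Mybpc3 at 5106 against 0.746 CPM, and the calcium release channel gene Ryr2 at 3616 against 0.666 CPM. Tnnt2 was 899 times higher in heart (exact 95% counting interval 787 to 1030.5), and Pln 1379 times. In the other direction Myh4 was 15765 times higher in skeletal muscle (interval 13623 to 18348), and Actn3, the calcium buffer gene Pvalb, Tnnc2 and Mylpf stood at 23926, 14725, 15927 and 10947 CPM in muscle, each under 1 CPM in heart. Myh4 and Myh6 belong to a family of close paralogs, and the counted Myh6 transcript is not in the annotation used, so its overlap with other genes was not checked.

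As lists, the 25 heart genes had a median log2 difference of heart over skeletal muscle of 6.17 and the 25 fast muscle genes one of -8.63, the highest and the lowest of 10000 random lists matched on expression. The 9 slow muscle genes had 3.51, with 6 higher in heart. Of the 22 sarcomere genes shared by both organs 4 were at least 2-fold higher in heart and 13 in skeletal muscle, with a median of -1.25 at percentile 1.67. All 18 fatty acid oxidation genes were higher in heart, at the top percentile, and the 9 endothelial genes were too, with 1.49. The respiratory chain list had 0.12, at percentile 87.8 of the random lists, and the glycolytic list -0.47, at percentile 10.1. Of the splicing regulators 24 of 36 were higher in heart, with a median of 0.19 at percentile 99.0. Lists of other organs lay as far out, the neuronal one with 0.37 at percentile 99.8 and the kidney one with 0.40 at 99.985, as did the red cell list with 2.75 at 99.99, while the ribosomal list with -0.68 and the adipocyte list with -2.11 lay below every random list. Of 4034 genes with 50 CPM in either organ, 278 were at least 4-fold higher in heart and 328 in muscle. Each side is 1 library, so no test between them was run, and with scaling by library size alone the counts were 467 in heart and 220 in muscle, so the larger side depends on the scaling, and the median log2 difference rose by 0.56. This pair was first planned across species and was taken up in mouse alone once the other species' genes proved to be unnamed.

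Across mouse, chicken, lizard and frog, organs were compared within each species in the number of genes that reached 1 CPM. More genes did so in brain than in skeletal muscle in all 4 species. A mean of 13059.5 genes ± 631 (SD, n = 4 species) reached 1 CPM in brain, 12619.8 ± 863 (n = 4) in kidney, 11657 ± 689 (n = 4) in heart, 10949.7 ± 619 (n = 3) in liver and 10164.5 ± 1139 (n = 4) in skeletal muscle. Brain had the most genes in 3 of 4 species, with kidney first in frog, and skeletal muscle had the fewest in 3 of 4, with liver last in mouse. A permutation test of organ ranks within species gave p = 0.00019, adjusted p = 0.000285 over 3 tests. With chicken and lizard alone, whose libraries share 1 set of mappable positions, the permutation p was 0.101, where the smallest possible is 0.0167.

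The 10 most abundant genes took the smallest share of counts in brain in all 4 species. That share averaged 9.23% ± 8.26 (SD, n = 4) in brain, 13.6% ± 8.14 (n = 4) in kidney, 25.6% ± 10.8 (n = 4) in heart, 26.2% ± 8.73 (n = 3) in liver and 43.6% ± 12.3 (n = 4) in skeletal muscle. Skeletal muscle had the largest share in 3 of 4 species, from 30.3% (exact 95% interval 30.27 to 30.30) in mouse to 59.4% (59.35 to 59.38) in lizard, while in chicken heart, at 41.6%, passed skeletal muscle, at 39.0%. In mouse the single largest were Alb, serum albumin, with 8.35% of liver counts, Gpx3, a secreted kidney peroxidase, with 3.95% of kidney counts, and Atp2a1, the fast muscle calcium pump, Acta1, skeletal actin, and Myh4, with 6.24%, 5.95% and 5.68% of skeletal muscle counts. A permutation test of organ ranks within species gave p = 0.00077, adjusted p = 0.00077 over 3 tests, and 0.227 with chicken and lizard alone.

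**Figure D2:**
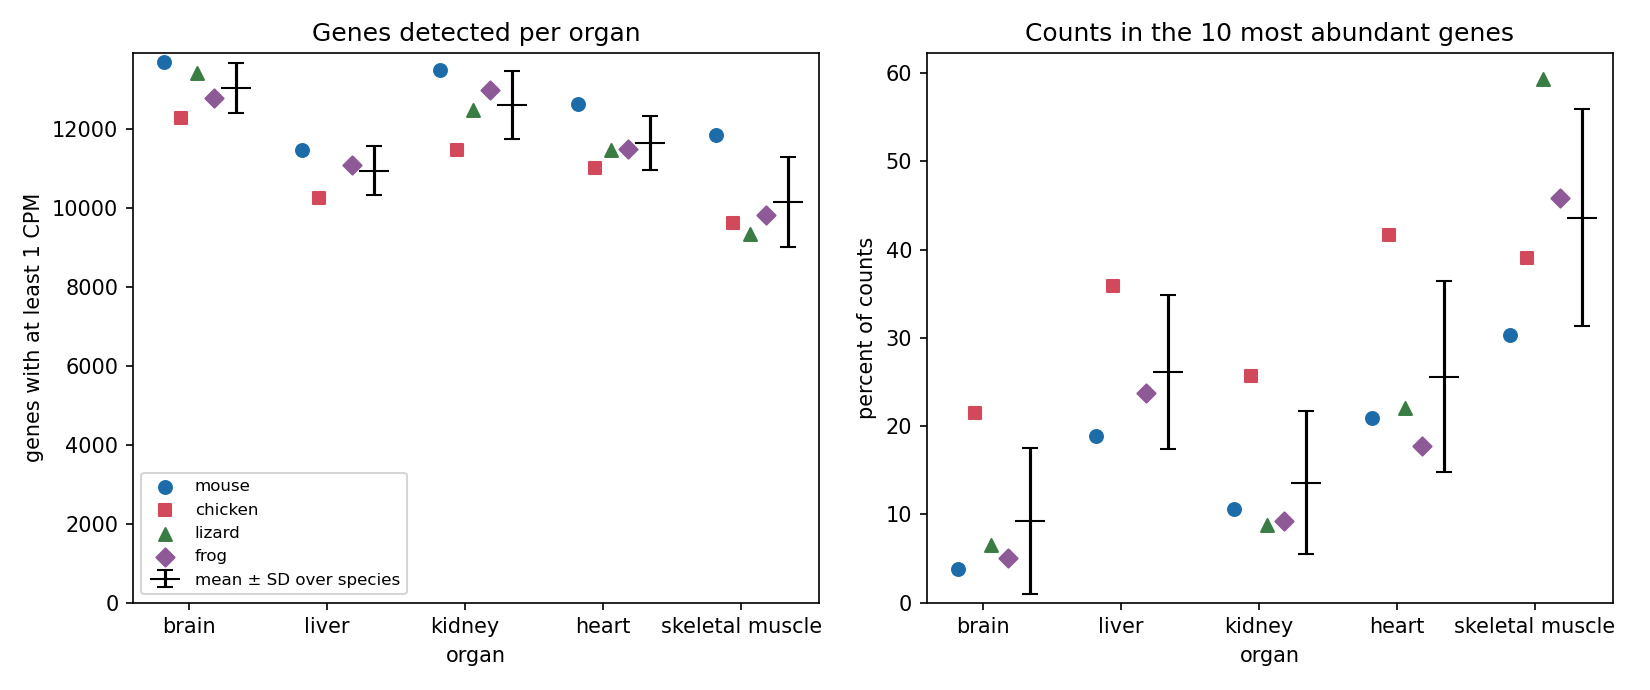
Number of genes with at least 1 CPM (left) and percent of counts in the 10 most abundant genes (right) for each organ, 1 point per species with the mean and SD over mouse, chicken, lizard and frog as black bars. Skeletal muscle lies below brain in genes and above it in share in all 4 species.

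Heart and skeletal muscle were the most similar pair of organs in all 4 species. Pearson's r across genes of log2 CPM with 1 added was 0.899 in mouse, 0.840 in chicken, 0.849 in lizard and 0.839 in frog, where genes are not independent replicates. The pair exceeded the mean of the other pairs by 0.164 on average, and an exact permutation test over 6000 choices of 1 pair per species, one-sided, gave p = 0.000167, the smallest possible, and adjusted p = 0.000285. With chicken and lizard alone the excess was 0.151, with exact p = 0.0167. Brain and liver were the least similar pair in mouse, chicken and frog, with r of 0.576, 0.602 and 0.532, and brain and skeletal muscle in lizard, with 0.629.

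**Figure D3:**
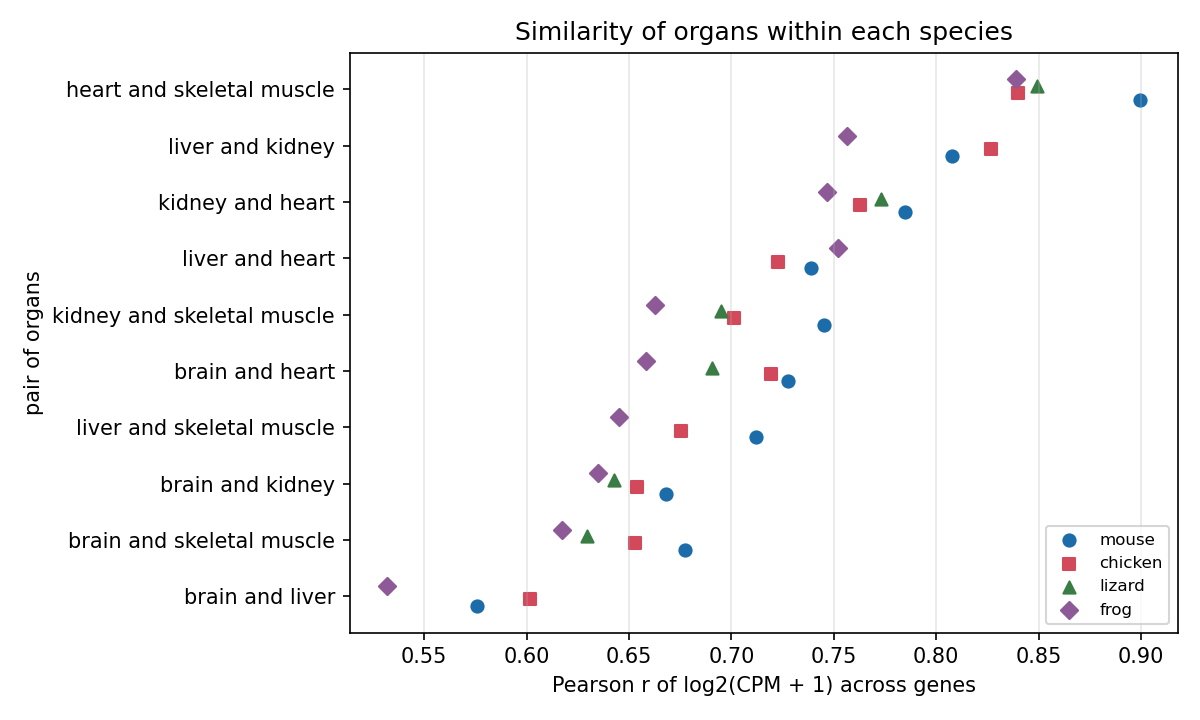
Pearson correlation across genes of log2 CPM (1 added) for each pair of organs in mouse, chicken, lizard and frog. Heart and skeletal muscle give the highest value in each species, 0.899, 0.840, 0.849 and 0.839.

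Brain had the most organ-enriched genes in all 4 species, those with at least 10 CPM and at least 8 times every other organ, 1 CPM added. The rule leaves out genes shared with another sampled organ, so the counts depend on which organs were sampled. Heart and skeletal muscle, the most similar pair, leave out genes they share, and in lizard no liver library leaves out genes of the other organs. Brain had 1114 of 1987 in mouse, 884 of 1400 in chicken, 1146 of 1792 in lizard and 882 of 1682 in frog. Kidney had 357, 204, 460 and 403, liver 338, 153 and 216 where it was sampled, skeletal muscle 98, 94, 99 and 104, and heart 80, 65, 87 and 77. At 4 times every other organ the totals were 2869 in mouse, 2245 in chicken, 2846 in lizard and 2537 in frog.

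Liver-enriched genes of frog were found in the frog heart library at a near constant fraction of their liver level. The 30 most abundant ones stood in heart at a median of 2.04% of their liver level, all of them between 1.35% and 3.94%. Of the next 70 such genes 60 lay within 2-fold of that median, 2 below and 8 above. The 100 genes took 32.2% of liver counts and 0.739% of heart counts. In frog skeletal muscle the first 30 stood at a median of 0.0937% of liver, with 83.3% of them and 58.6% of the next 70 within 2-fold of it, and in chicken heart the chicken ones at 0.0433%. By the first 30 genes, frog liver genes in heart were singled out as the most uniform among 72 pairs of organs, and those in skeletal muscle came next. In mouse, 71.4% of the next 70 liver genes lay within 2-fold of the first genes' median in heart and 65.7% in skeletal muscle. Liver RNA or reads carried into the mouse libraries were not tested for. Without the frog heart library the permutation p for genes detected was 0.00188 and for the share of the 10 most abundant genes 0.00075.

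**Figure D4:**
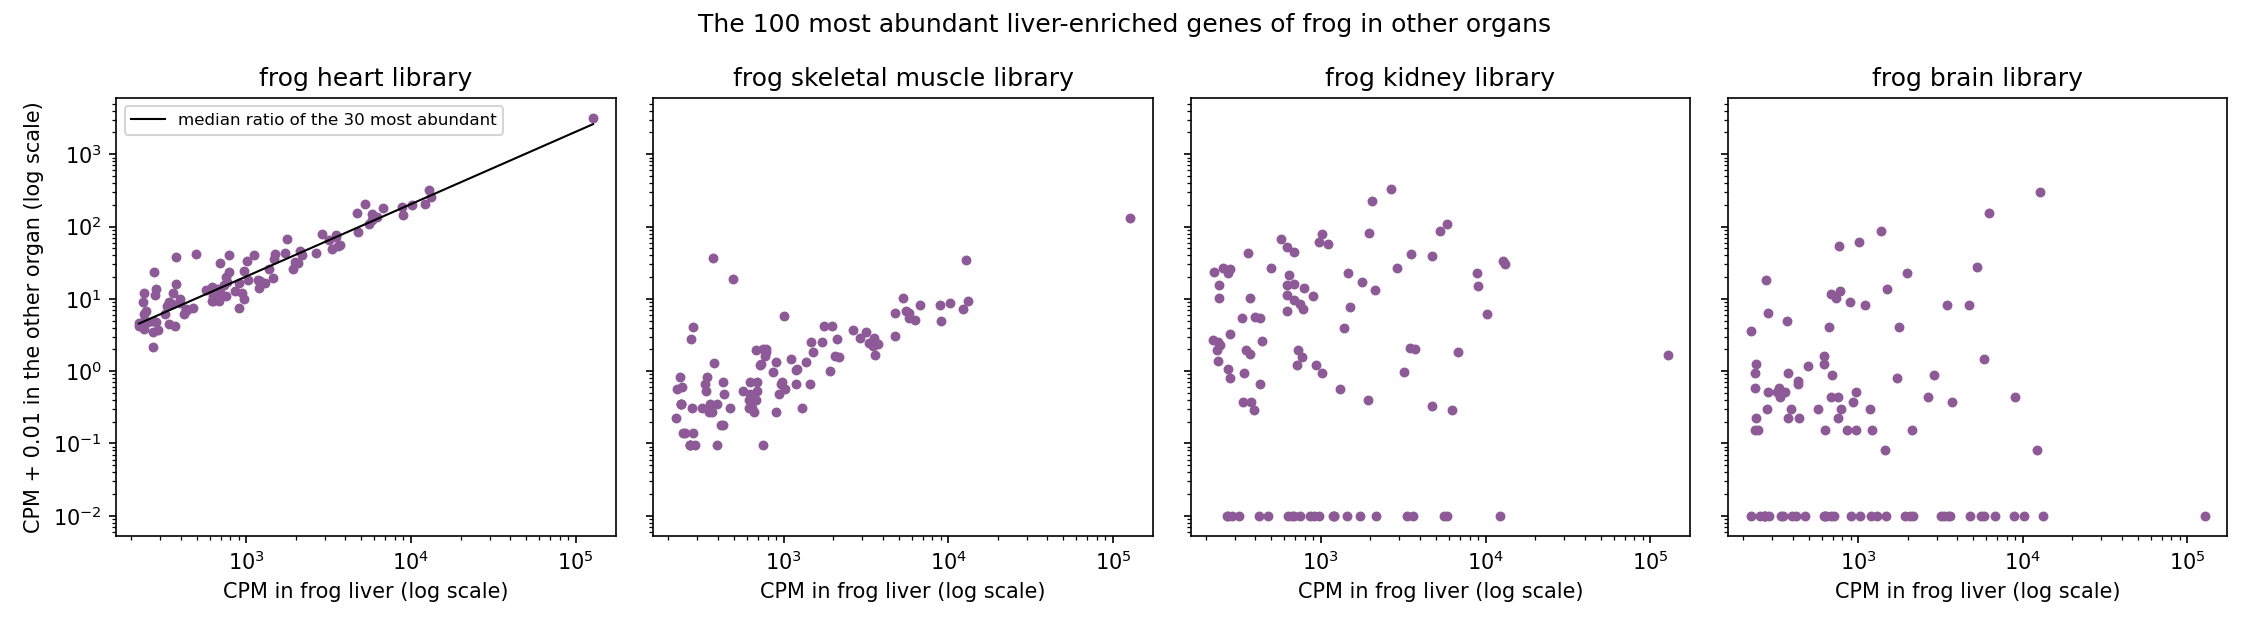
Level of the 100 most abundant liver-enriched frog genes in liver (CPM, log scale) against their level in the heart, skeletal muscle, kidney and brain libraries (CPM with a small constant added, log scale), 1 point per gene. In heart the genes follow the black line, the median of 2.04% of the liver level over the first 30 genes, in skeletal muscle they lie lower and scatter more, and in kidney and brain they scatter widely.

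Pufferfish brain, the only organ of that species, had 15884 genes with at least 1 CPM. Its 10 most abundant genes took 5.85% of counts (exact 95% interval 5.83 to 5.86), against 5.11% in frog brain and 21.5% in chicken brain.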

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

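The 10 most abundant genes took 21.5% of counts in chicken brain, far above the other species' brains, which ranged from 3.79% to 6.54%. In chicken kidney they took 25.7%, far from the other kidneys at 8.74% to 10.6%. Both were picked out by the gap to the nearest other species relative to the whole range over 4 species, where 16 groups were examined and chance gives about 1 in 20.

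The difference between heart and skeletal muscle in that share was 2.60 percentage points in chicken, with heart above muscle, while muscle was above heart in mouse, lizard and frog. Each value is 1 library, and this difference between species was not tested. In chicken, 3 genes were among the 10 most abundant in all 5 organs and together took 13.6% of brain counts, 13.6% of liver, 12.8% of kidney, 19.7% of heart and 12.8% of skeletal muscle counts. No gene was in the top 10 of every library in mouse, lizard or frog. Without these 3 genes the share was 10.7% in chicken brain, 18.4% in kidney, 33.1% in heart and 35.4% in skeletal muscle, values computed after the others were seen. No explanation was tested for them.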

How the results depend on the processing

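Over the alternatives run, 134 of 147 recomputed main results kept their direction and their side of the threshold, or stayed within 1.5 times for a count. That bound is wide. With library size alone, genes higher in brain than in skeletal muscle rose from 7614 to 10656 and count as kept. Against kidney, 7509 higher and 7606 lower in brain count as kept too, although the larger side changed. The named genes recomputed were the 4 with the largest change in each list and the 8 regulators with the smallest adjusted p. Most of their calls were thus bound to be kept. Regulators outside the 8, such as Ptbp3, were recomputed only where they were among those 4. Of 2438 recomputed tests of named genes 2381 kept their call or lack of one, 50 no longer passed, 6 newly passed and 1 turned. That one is Rbfox1, higher in skeletal muscle than in brain with TMM and higher in brain with library size alone, at a log2 difference of 0.20, through the shift of all genes with that scaling. With glmTreat, which asks for a change beyond 2-fold and so calls fewer genes by construction, 5893 genes were higher and 4855 lower in brain against liver, 5229 higher and 4679 lower against kidney, 4868 higher and 4364 lower against heart, and 5159 higher and 4880 lower against skeletal muscle. With library size alone 4939 genes were lower in brain against skeletal muscle, and 467 genes were at least 4-fold higher in mouse heart than in skeletal muscle and 220 lower. At 4 times every other organ, a wider definition, organ-enriched genes came to 2869 in mouse, 2245 in chicken, 2846 in lizard and 2537 in frog. With chicken and lizard alone, fewer species by construction, the permutation p was 0.101 for genes detected and 0.227 for the share of the 10 most abundant genes. Leaving out each species in turn gave 0.00176 to 0.00763 and 0.00411 to 0.0178 for those tests. The subset of chicken and lizard, thinning at 1 CPM and the other scaling of heart against skeletal muscle were chosen after seeing the data. The DESeq2 Wald test shared 68.5% to 81.2% of each set of calls and DESeq2 size factors 93.1% to 99.97%. Library size alone shared 63.8% to 100% and glmTreat 59.3% to 72.9%. Of 192 recomputed list tests 55 no longer passed, all with the correlation estimated, which with 1 residual degree of freedom could hardly call any list. Another 2 newly passed with DESeq2 size factors, the heart list against skeletal muscle and the immune list against liver. Leaving out a brain library leaves no residual degree of freedom, so only values were recomputed, and of 820 for named genes none that was called turned. Depth limits genes near 1 CPM, where counting error reached 62.8%, in lizard kidney.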

Other observations

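Beyond the parenchyma, mouse organs differed in the genes of other cell types. Endothelial genes were higher than in brain for 8 of 9 in heart, 8 in skeletal muscle and 7 in kidney, while liver had 3 higher and brain 4. The vascular receptor gene Kdr stood at 326 CPM in heart, 56.5 in skeletal muscle and 56.0 in kidney against 16.7 in brain. Matrix genes were higher in heart for 10 of 10, in skeletal muscle for 9, in kidney for 8 and in liver for 6, with the collagen gene Col3a1 at 671 CPM in skeletal muscle and 500.4 in heart against 8.03 in brain, and the fibronectin gene Fn1 at 4405 CPM in liver. All 8 smooth muscle genes were higher in heart and in skeletal muscle, 7 in kidney and 4 in liver, such as Smtn at 257 CPM in heart against 16.1 in brain. Of 5 red cell genes measured, all were higher in heart and 4 in each other organ, with the globin gene Hbb-bs, one of close paralogs, at 401 CPM in heart, 88.1 in kidney, 45.9 in liver and 16.8 in brain. Adjusted over the list alone, the counts were the same except for 3 red cell genes in liver. Camera gave adjusted p of 6.64e-04 for the matrix, 0.00639 for the smooth muscle, 0.00663 for the red cell and 0.0116 for the endothelial list in heart, and 0.529 to 0.583 with an estimated correlation. The estimated correlation of the endothelial list, 0.222, was above the preset 0.01, so its camera call rests on that preset. With scaling by library size alone, 5 smooth muscle, 5 matrix and 7 endothelial genes were higher in brain than in liver, against 3, 4 and 2 lower, and against skeletal muscle 3 endothelial genes and 1 red cell gene were higher in brain, with 6 and 2 lower.

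Immune genes were higher in liver for 10 of 13 and lower in 1, in heart 7 and 2, in kidney 6 and 6 and in skeletal muscle 6 and 4, with the antigen presentation gene Cd74 at 306 CPM in kidney against 7.53 in brain. Pituitary and choroid plexus genes were higher in brain for 7 of 9 against liver, 6 against kidney and 8 against heart and skeletal muscle, with growth hormone, Gh, at 31.6 CPM and prolactin, Prl, at 7.30 CPM in brain. Exocrine pancreas genes were few, with 5 of 8 higher in liver and 2 in brain, and 1, 1 and 0 higher in kidney, heart and skeletal muscle, where brain had 3, 4 and 3. The elastase gene Cela1 stood at 73.2 CPM in kidney against 1.15 in brain. Of 14 immediate early and heat shock genes, brain held 3, 9, 6 and 6 above liver, kidney, heart and skeletal muscle and 9, 4, 6 and 8 below, with Fosb, induced by neuronal activity, at 33.1 CPM in brain and 0.256 in kidney and Egr1 at 397 and 17.0 CPM. With scaling by library size alone, these last counts were 7 above and 4 below for liver, 8 and 6 for heart and 7 and 6 for skeletal muscle, and immune genes higher in brain numbered 3 against liver, 6 against heart and 7 against skeletal muscle, with 8, 6 and 4 lower, and pancreas genes higher in brain numbered 5 against skeletal muscle. Only the pancreas counts changed when adjusted over the list alone, with 2 genes higher in brain against kidney and against skeletal muscle. Off their own organ, the kidney list had 10 genes higher in brain and 5 lower against liver, 8 and 13 against heart, and 11 and 9 against skeletal muscle. With an estimated correlation the adjusted p of every list in these paragraphs was 0.529 or more.

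The tests for misassigned adipocyte reads and for 1 ratio over the adipocyte genes were chosen only after the result was seen, removal of the 100 most abundant genes and thinning at 1 CPM after other values had been seen, and the 2 tests on frog heart after the 30 most abundant genes had been seen but before the next 70 were. All 8 adipocyte genes were higher in mouse kidney, heart and skeletal muscle than in brain, and 6 in liver. Adipoq, which encodes the fat hormone adiponectin, stood at 32.2, 11.6 and 44.4 CPM in kidney, heart and skeletal muscle with no read in brain, and Cfd at 290, 101.3 and 395 CPM (plain CPM). Of 8 further adipocyte genes fixed before their values were seen, 6 were above the brain level in all 3 organs. That passed the bound set for fat attached to the organ pieces, more than 50% of the list, though 2 of the 8 are highest in brain and 2 in liver. The share of all genes above brain in these organs was not computed. The test therefore cannot tell attached fat from other expression outside brain. Fat of the same make-up in each organ cannot be told apart from fat that differs, since 78.6% of the 14 genes of both lists above brain had a ratio of kidney to skeletal muscle within 2-fold of their median of 0.730, between bounds of 90% and 50%, with Lep at 0.0902 and Ucp1, of brown fat, at 5.76. Reads misassigned from another mouse library of this series are argued against. The highest Adipoq level among these libraries is 3.83 times the lowest of the 3 organs, far from what a source of stray reads would need. No fat library is in the series, so this could be foreseen, and a source outside the series was not tested.

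Skeletal muscle had fewer genes at 1 CPM than brain in 4 of 4 species, by 2895 on average. Depth is argued against as the whole cause. In chicken, lizard and frog skeletal muscle was deeper than brain, with 31178305, 43959301 and 23202273 counts against 27834383, 36877498 and 13803809. Lower depth in muscle therefore does not apply there. In mouse, skeletal muscle, at 55730020 counts, lay between the brain libraries. Each species was also thinned to its smallest library. The difference in genes with at least 5 reads, another measure, was then 83.5% ± 1.89 (SE paired over 4 species) of that at 1 CPM. The difference in genes at 1 CPM was 99.5% ± 0.375 of that before thinning, where CPM is already scaled to depth. Without the 100 most abundant genes of each library 51.0% ± 4.18 (SE) remained, close to the bound of 50% that had been set. The part remaining was 45.9% in mouse, 60.6% in chicken, 43.9% in lizard and 55.3% in frog. The removal thus narrowed the difference in each species and closed it in none. Whether a few abundant genes taking most counts are the main cause cannot be told from these values. A difference between the organs in the number of genes expressed stays open as well and was not tested.

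The liver genes in the frog heart library may come from liver RNA or reads carried into it, or from expression by heart. Of the 70 liver-enriched genes ranked below the first 30, 85.7% lay within 2-fold of the first genes' median ratio, short of the 90% that carry-over had been set to need and above the 50% that would have argued against it. The interquartile range of the log2 ratio over these 70 genes was 0.79 (bootstrap 95% interval 0.60 to 1.12), below the 2 set for expression by heart, with an interval that reaches past the bound of 1 set against it. That interval was added after the value was seen, and without it the value lies under that bound. These explanations cannot be told apart from 1 library, and the mappable positions of frog heart and liver differ.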
